A study of Homo sapiens with 38 samples.

How the data were processed

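RNA was measured in 38 libraries of CD4 T cells sorted from human spleen. Per the labels' protocols, spleen was dissociated mechanically, mononuclear cells were enriched on a Ficoll gradient, subsets were sorted on a BD Aria II, RNA was extracted with a column kit, and stranded total RNA libraries for very low input were prepared with a Clontech SMARTer Pico kit. The deposited files give whole-number counts per gene symbol, 33458 symbols in each file, and the submitters' processing notes name Trimmomatic 0.32, STAR 2.5.2a, DESeq2 1.20.0 and the build hg38 without saying which step each served. The counting program, its annotation and its use of strand are not given in the sources used here, so reads of overlapping, antisense or near-identical genes may be assigned uncertainly. Total counts lay between 334325 and 338135 per library (median 336522), a spread of 1.14%, so the libraries look to have been brought to a common depth before deposit, and how is not given in the sources used here. The values are whole numbers and were tested as counts, and whether they were scaled before deposit is left open.

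At this depth 1 count was worth 2.97 CPM (the count divided by the library's normalised total and scaled to 1e6). A group with 0 counts in every library was given a floor of 3 counts per library, or 8.91 CPM, and a fold against such a group is a lower bound against that floor. Where a group held only 1 to 3 counts, CPM levels are given and no fold. Floors cover counting error only, because PCR copies are not independent molecules. Between 7655 and 18628 symbols had a count (median 13493). No 2 files held identical values, and the smallest chi-square per degree of freedom between libraries of a subset was 3.28, so no library was counted as a repeat of another.

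The labels put each library in 1 of 4 subsets and name its specimen: naive CD4 T cells (5 libraries), nonGC Tfh (5), SLAMhi GC-Tfh (14) and SLAMlo GC-Tfh (14), from 14 specimens. Specimens 1, 2, 9, 10 and 14 had all 4 subsets, and the 9 others had SLAMhi and SLAMlo only. The specimen codes begin with 1 of 3 digits, whose meaning is not given in the sources used here (5, 5 and 4 specimens).

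Genes were tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 (robust glmQLFit), TMM normalisation and Benjamini-Hochberg adjustment at 0.05, after filterByExpr by group (minimum count 10, minimum total 15). The designs were fixed before the data were examined. SLAMhi and SLAMlo were compared over the 28 libraries of 14 specimens, and the other 5 comparisons were taken from 1 fit of the 20 libraries of the 5 specimens with 4 subsets. Specimen was not a term of these fits, and the fit with specimen as a block was named beforehand as a second choice. SLAMhi and SLAMlo libraries of a specimen deviated together from their subset means (median r = 0.38, lowest 0.15, above 0.1 in 14 of 14 specimens, each best with its own partner), and the specimen code says that they come from the same specimen, so they are paired. Blocked values stand beside a result where they change a call or move a count by over 1.5 times. XIST, TSIX and Y-linked genes, 73 symbols in all, were left out of the tests. Printed levels are mean CPM ± SD over specimens, scaled by TMM over all 38 libraries, and log2 fold changes are ± SE. Adjusted p-values of single genes are from edgeR, and a count such as 13 of 14 gives the specimens in which the level moved in the stated direction.

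A total of 32 gene lists, with 582 of 621 entries among the symbols, were fixed before the data were examined. They covered the Tfh programme, helper cytokines and costimulation, SLAM family and adaptors, migration and positioning, naive and quiescence, immediate early genes, heat shock, TCR and NFAT response, NF-kB targets, cell cycle, Treg and Tfr, Th1 and cytotoxic CD4, Th2, Th17, memory and tissue residence, inhibitory receptors, interferon response, apoptosis, glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein response, ribosomal proteins, mitochondrially encoded genes, nuclear-retained RNA, and markers of B cells, germinal centre B cells, plasma cells, myeloid cells, stroma, CD8 and NK cells, and erythroid cells and platelets. Lists with at least 3 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 3) with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members were counted with adjustment over all genes and adjusted over the list alone.

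Genes were named by a rule fixed before the data were examined: the sort genes, and per comparison the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM and the same direction in at least 12 of 14 specimens (at least 11 of 13 in the repeat without specimen 9, and every specimen elsewhere), leaving out HLA, antigen receptor and clone-based symbols. Up to 4 members per list with the smallest adjusted p were named too. Some genes that this rule takes in are not reported here. PDCD1 was not analysed here. Symbols were matched to GENCODE 29 on hg38 for coordinates (23862 matched, 23823 with unique coordinates).

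Each library was compared with the 4 subset centroids over the 500 symbols that varied most between centroids (mean count above 10), leaving its own specimen and specimen 9 out of the centroids. That check, made after the data were examined, put 3 of specimen 9's libraries nearest another subset. The labels were kept in every fit, and each comparison was repeated without specimen 9, which was named beforehand as a leave-one-out choice for the 5 comparisons with 4 subsets and was singled out, and added for SLAMhi against SLAMlo, only after its values were seen. Leaving out a discordant specimen raises counts of changed genes by itself. In the repeat of SLAMhi against SLAMlo, named genes were taken from the blocked fit, also a choice made after the data were examined. On sex-linked genes, libraries of 0 of 14 specimens disagreed with each other.

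A shift between subsets was tested on independent specimens. Genes with adjusted p under 0.05 and a log2 fold change beyond 1 between SLAMlo and nonGC were taken from the specimens with 4 subsets, and the median SLAMhi minus SLAMlo difference over them was tested in the 9 others by an exact two-sided sign-flip permutation test. The other choices named beforehand were the block, DESeq2 1.42.0, RLE size factors, no filter on low counts, code prefix as a covariate, subsets of the specimens, leaving out each specimen, and all libraries in 1 fit. Added after the data were examined were limma on log2 CPM, the fits without specimen 9, the fits without specimens 3, 9 and 13, and leave-one-out fits of SLAMhi against SLAMlo. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for counting and drawing.

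The fits were tested on simulated counts in which 200 genes were changed. For SLAMhi against SLAMlo over 14 specimens (4870 genes) the fit recovered 56% of 2-fold and 97% of 4-fold changes, and 79% and 99% with the block, with 2 and 6 false calls. For nonGC against naive, 5 specimens (5945 genes) gave 5% of 2-fold and 74% of 4-fold changes, and 4 specimens (5980 genes) gave 1% and 46%, or 6% and 63% with the block. The simulated spread was estimated without a subset term, so real differences between subsets entered it as noise. These shares therefore do not give the power of the fits. In this simulation, changes near 2-fold mostly went uncalled for nonGC against naive, and the other comparisons of 4 or 5 specimens were not simulated.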

Results

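Total RNA was profiled in 38 libraries of CD4 T cells sorted from 14 human spleen specimens. T follicular helper (Tfh) cells help B cells in lymphoid follicles. The series concerns splenic Tfh cells that carry SLAM and the follicle's mantle zone, which surrounds the germinal centre (GC). SLAM, the product of SLAMF1, is a receptor that binds itself on neighbouring lymphocytes. Naive CD4 T cells (5 libraries) and non-naive cells sorted as positive for CXCR5 and PD1, called nonGC Tfh in the labels (5), were profiled. Cells high in both markers were sorted by SLAM into SLAMhi and SLAMlo GC-Tfh (14 each). Each library held between 334325 and 338135 counts. The symbols with a count ranged from 7655 (SLAMhi, specimen 3) to 18628 (SLAMlo, specimen 13). Replicates are specimens that the labels name separately. The p-values of single genes measure the spread between libraries of a subset, with the pairing by specimen used only where the block is named. Those of lists, from camera, set members against the other genes under a preset or estimated correlation. They do not measure the spread between specimens. Sign-flip p-values measure the spread of paired differences between specimens.

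In 1 specimen the expression profiles and the labels did not match. All 34 libraries of the other 13 specimens correlated best with the centroid of the subset on their label. In specimen 9, the library labelled naive correlated best with the SLAMlo centroid (r = 0.743, against -0.603 with naive). The library labelled nonGC correlated best with the naive centroid (r = 0.831, against 0.347 with nonGC), and the library labelled SLAMlo with the nonGC centroid (r = 0.694, against -0.564 with SLAMlo). The library labelled SLAMhi matched its own subset (r = 0.534). These correlations run across genes, which are not independent replicates. Over 195 genes that vary between specimens, 4 of 4 libraries of specimen 9 matched their own specimen best, as did 16 of 16 libraries of specimens 1, 2, 10 and 14. The labels were kept. Every comparison is given over all specimens as labelled and again without specimen 9, which was singled out after its values were seen.

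**Figure D1:**
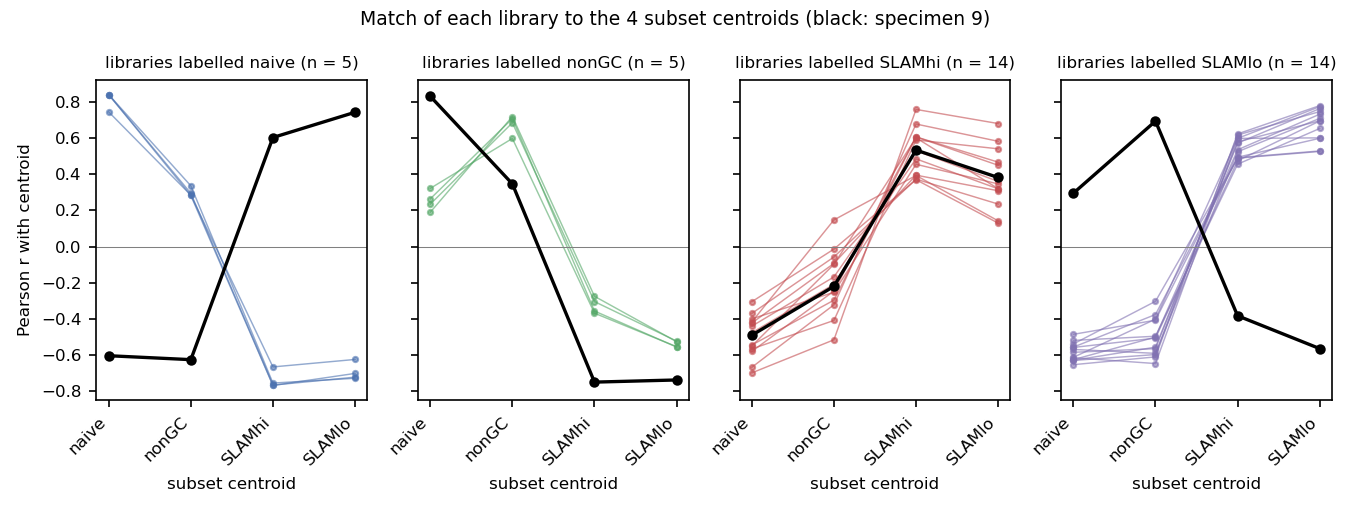
Pearson correlation (y axis) of each library with the 4 subset centroids (x axis), 1 panel per labelled subset and 1 line per library, with specimen 9 in black. The library labelled naive in specimen 9 reached r = 0.743 with the SLAMlo centroid, while the 4 other naive libraries lay highest at the naive centroid.

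The main comparison asked how SLAMhi differed from SLAMlo GC-Tfh, over 14 specimens as labelled. RUNX3, a transcription factor of effector and cytotoxic T cells, was higher in SLAMhi at 335 ± 132 against 129 ± 51.5 CPM (n = 14). Its log2 fold change was 1.37 ± 0.20 (edgeR adjusted p = 2.54e-04, 14 of 14 specimens). CXCR3, a chemokine receptor of type 1 effector T cells, was higher at 85.6 ± 61.7 against 28.6 ± 18.4 CPM (log2 1.55 ± 0.35, edgeR adjusted p = 0.0224, 13 of 14). STOM, a membrane scaffold protein, stood at 219.5 ± 66.7 against 93.8 ± 40.1 CPM (log2 1.22 ± 0.20, edgeR adjusted p = 7.81e-04, 14 of 14). SLAMhi held less PTPN14, a protein tyrosine phosphatase, at 33.4 ± 35.4 against 203 ± 128 CPM (log2 -2.60 ± 0.49, edgeR adjusted p = 0.00782, 14 of 14). The imprinted gene PEG10 (log2 -2.88 ± 0.57, edgeR adjusted p = 0.0118, 14 of 14) and the neurotrophin receptor NTRK3 (log2 -2.32 ± 0.43, adjusted p = 0.00521, 13 of 14) were lower too. On hg38, RUNX3 lies on chromosome 1, 24899511 to 24965121, CXCR3 on chromosome X, 71615916 to 71618517, STOM on chromosome 9, 121338988 to 121370304, and PTPN14 on chromosome 1, 214348696 to 214552449, each a protein-coding gene.

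Also among the 10 largest rises were FLNA, an actin crosslinker (log2 1.14 ± 0.26), the TGF-beta co-receptor TGFBR3 (1.35 ± 0.34), SAMHD1 (1.09 ± 0.25) and PREX1 (0.96 ± 0.19). FAM49B (0.93 ± 0.20), CAPN2 (0.86 ± 0.19) and the IL-10 receptor chain IL10RA (0.83 ± 0.17) completed them, and the edgeR adjusted p of these 7 lay between 0.00746 and 0.0474. The 10 largest falls included KSR2, a member of the Tfh list, at 50.7 ± 31.6 against 146 ± 92.9 CPM (log2 -1.52 ± 0.36, edgeR adjusted p = 0.0386, 13 of 14). IKZF2, which encodes the transcription factor Helios, stood at 75.8 ± 40.4 against 206 ± 129 CPM (log2 -1.45 ± 0.35, edgeR adjusted p = 0.0386, 12 of 14). XXYLT1 (log2 -1.91 ± 0.34), SETD7 (-1.76 ± 0.32), SMPD3 (-1.69 ± 0.33), GAB2 (-1.47 ± 0.37) and NFIA (-1.28 ± 0.29) fell too, with edgeR adjusted p between 0.00306 and 0.0474. SLAMF1 itself, a sort gene (chromosome 1, 160608100 to 160647295), stood at 86.9 ± 39.2 against 46.6 ± 22.9 CPM (log2 0.89 ± 0.26, 12 of 14). It did not pass (edgeR adjusted p = 0.125), but did with specimen as a block (adjusted p = 0.0234). CXCR5 (51.1 ± 23.7 against 37.5 ± 19.6 CPM, edgeR adjusted p = 0.679), CD4 (516 ± 161 against 507 ± 152 CPM, 0.985) and PTPRC (1356 ± 225 against 1329 ± 265 CPM, 0.978) did not pass either.

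**Figure D2:**
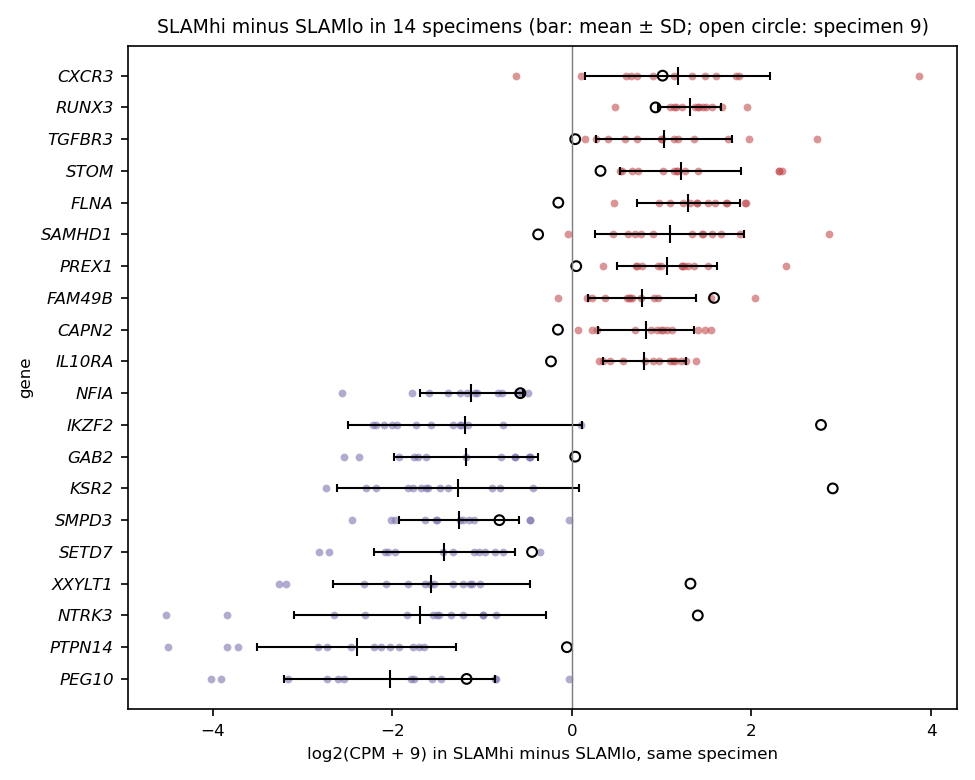
Difference between SLAMhi and SLAMlo in the same specimen on the log2(CPM + 9) scale (x axis) for 20 genes (y axis), with 1 point per specimen, the mean ± SD as a bar and specimen 9 as an open circle. RUNX3 was higher in SLAMhi in 14 of 14 specimens and PTPN14 lower in 14 of 14.

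In all, 38 of 5158 tested genes changed (13 higher and 25 lower in SLAMhi). With specimen as a block 283 changed (161 and 122), including all 38, and DESeq2 called 73. Each of the 38 had the same direction in the mean of each of the 3 code prefixes. They were called over these same specimens, so this is not separate support. Leaving out specimen 9 gave 78 genes, specimen 4 gave 43, and any 1 of the 12 others gave 16 to 25. The 5 specimens with 4 subsets alone gave 0 in edgeR (193 at an unadjusted p under 0.05).

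As groups, mitochondrially encoded transcripts were lower in SLAMhi (camera adjusted p = 4.66e-08, adjusted p = 0.123 with an estimated correlation). Of 14 members 2 fell, 10 adjusted over the list alone and 11 with the block. Among them, MT-ND4 stood at 5075 ± 1072 against 7184 ± 1419 CPM (log2 -0.51 ± 0.12, edgeR adjusted p = 0.0386, 14 of 14). Cell cycle genes were higher as a list (camera adjusted p = 1.24e-06, adjusted p = 0.0374 with an estimated correlation). Of 9 members 0 rose over all genes, 6 adjusted over the list alone and 4 with the block. The proliferation marker MKI67 stood at 209 ± 155 against 50.1 ± 68.8 CPM (edgeR adjusted p = 0.116, 13 of 14). Migration and positioning genes were higher (camera adjusted p = 0.00150, adjusted p = 0.0374 with an estimated correlation). CXCR3 was the 1 of 16 that rose (1 adjusted over the list alone), and with the block 4 rose and 1 fell. Glycolysis genes were higher as a list (camera adjusted p = 0.00277, adjusted p = 0.0338 with an estimated correlation). Of 16 members 0 rose, 1 adjusted over the list alone and 3 with the block. The memory and tissue residence list was higher (camera adjusted p = 9.47e-05, adjusted p = 0.123 with an estimated correlation), with 0 of 9 members called, 2 adjusted over the list alone and 5 with the block. The Tfh programme was lower (camera adjusted p = 0.0263, adjusted p = 0.396 with an estimated correlation). KSR2 was the 1 of 26 members that fell. Adjusted over the list alone, 1 rose and 3 fell, and with the block 2 and 7.

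Without specimen 9, SLAMhi GC-Tfh held more ANXA1, an annexin, at 230.2 ± 190.4 against 46.4 ± 55.3 CPM (n = 13). Values of single genes here are from the blocked fit: ANXA1 had a log2 fold change of 2.46 ± 0.23 (edgeR adjusted p = 1.02e-10, 13 of 13). PRDM1, which encodes the repressor BLIMP1, stood at 176 ± 96.7 against 54.9 ± 37.3 CPM (log2 1.69 ± 0.21, edgeR adjusted p = 1.08e-07, 12 of 13). MKI67 stood at 209 ± 161 against 54.0 ± 70.04 CPM (log2 2.11 ± 0.46, 12 of 13), with edgeR adjusted p = 0.0104 with the block and 0.112 without it. Other large rises were PDE4B (log2 2.22 ± 0.24), INADL (2.17 ± 0.39), the myosin MYO1F (1.88 ± 0.33), ANK3 (1.72 ± 0.32), CSF1 (1.58 ± 0.30), CXCR3 (1.44 ± 0.28) and KLRB1 (1.44 ± 0.32). Of these, CSF1 (edgeR adjusted p = 2.92e-04 with the block, 0.386 without it) and KLRB1 (0.00189 and 0.0517) passed with the block only. B3GAT1, the enzyme that makes the CD57 epitope, was lower at 168 ± 192 against 439.8 ± 377 CPM (log2 -1.51 ± 0.22, 12 of 13), with edgeR adjusted p = 4.37e-05 with the block and 0.351 without it. PEG10 (log2 -2.81 ± 0.26), PTPN14 (-2.78 ± 0.23), NTRK3 (-2.44 ± 0.31) and IKZF2 (-1.62 ± 0.17) were lower. SLAMF1 passed with the block (edgeR adjusted p = 9e-04) and without it (0.0215), at 91.8 ± 36.2 against 44.1 ± 21.6 CPM (log2 1.05 ± 0.26, 12 of 13). Unblocked, that call was lost without specimen 1, 6, 11 or 13 (edgeR adjusted p for SLAMF1 of 0.0723, 0.0569, 0.0581 and 0.0580). On hg38, ANXA1 lies on chromosome 9, 73151757 to 73170393, PRDM1 on chromosome 6, 106086320 to 106109939, and MKI67 on chromosome 10, 128096659 to 128126385.

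This repeat gave 78 of 5048 genes (35 higher, 43 lower), 378 with the block (222 and 156), 130 by DESeq2, and 50 and 49 without specimen 8 or 11. The Tfh programme was lower (camera adjusted p = 1.27e-05, adjusted p = 0.0957 with an estimated correlation). Of 26 members 4 fell, 8 adjusted over the list alone with 2 up. With the block 13 fell and 2 rose (adjusted p = 0.0371 with an estimated correlation). TOX and TOX2, regulators of Tfh identity, stood at 271 ± 83.5 against 427 ± 78.3 CPM (edgeR adjusted p = 0.0119, 13 of 13) and 304 ± 147 against 624 ± 278 CPM (0.0191, 13 of 13). Memory and tissue residence genes were higher (camera adjusted p = 3.19e-05, adjusted p = 0.0897 with an estimated correlation). Of 9 members 2 rose, 4 adjusted over the list alone and 6 with the block.

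The comparison of nonGC Tfh with naive cells asked what marks Tfh outside the gate of high CXCR5 and PD1. Over 5 specimens as labelled, 1 gene of 6192 rose in edgeR, DUSP5, a phosphatase that acts on ERK, at 236 ± 55.7 against 77.7 ± 22 CPM. Its log2 fold change was 1.58 ± 0.28 (edgeR adjusted p = 0.0364, 5 of 5), and the call was lost without specimen 1, 2, 10 or 14 (edgeR adjusted p for DUSP5 of 0.303, 0.646, 0.709 and 0.510). The call was kept without specimen 9, which all the fits that lost it held. With specimen as a block 4 genes changed, DESeq2 called 27 (21 higher, 6 lower), and all libraries in 1 fit gave 10 (8 and 2). Without specimen 9 (n = 4), MAF, a transcription factor of Tfh and other effector cells, stood at 635 ± 83.2 against 27.1 ± 6.34 CPM (log2 4.53 ± 0.25, edgeR adjusted p = 4.43e-12, 4 of 4). The inhibitory receptor TIGIT rose to 122 ± 4.57 against 5.60 ± 1.81 CPM (log2 4.36 ± 0.36, edgeR adjusted p = 2.14e-08, 4 of 4). CXCR5, a sort gene that guides T cells into follicles, stood at 54.6 ± 30.6 against 0.897 ± 1.79 CPM (edgeR adjusted p = 1.91e-04, 4 of 4). IFNG, the type 1 cytokine, had 0 counts in naive cells and 24.7 ± 13.5 CPM in nonGC Tfh, at least 2.78-fold above the floor (edgeR adjusted p = 0.0104, 4 of 4). GNAO1, a G protein subunit with 0 naive counts, was at least 8.37-fold higher at 74.6 ± 48.7 CPM (edgeR adjusted p = 0.00765, 4 of 4). TGFBI was at least 4.69-fold higher at 41.8 ± 21.8 CPM, and LINC00892 at least 1.89-fold at 16.8 ± 9.88 CPM, both in 4 of 4 specimens. On hg38, DUSP5 lies on chromosome 10, 110497838 to 110511544, CXCR5 on chromosome 11, 118883766 to 118897799, and IFNG on chromosome 12, 68154768 to 68159747.

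Other large rises were PLXND1 (185 ± 61.9 against 3.33 ± 2.95 CPM), the metalloprotease ADAM19 (184 ± 76.1 against 5.57 ± 2.98 CPM), KLRB1 (68.5 ± 40.9 against 0.747 ± 1.49 CPM), TMEM200A (41.0 ± 8.34 against 0.747 ± 1.49 CPM) and ST8SIA1 (93.7 ± 19.2 against 2.31 ± 2.99 CPM). Their edgeR adjusted p lay between 7.57e-08 and 0.00137. DACT1 fell to 0.775 ± 1.55 against 86.1 ± 27.0 CPM, and the egress receptor S1PR1 fell too (log2 -2.71 ± 0.56, edgeR adjusted p = 0.00733, 4 of 4). PECAM1 (log2 -3.91 ± 0.76), AK5 (-3.78 ± 0.70), KLF7 (-3.70 ± 0.61), CD55 (-3.07 ± 0.47), RIN3 (-3.05 ± 0.50), NET1 (-2.93 ± 0.60), PITPNM2 (-2.78 ± 0.68) and VIPR1 (-2.46 ± 0.66) fell as well. In all 132 genes rose and 60 fell, 352 changed with the block, and 82, 77 and 108 without specimen 1, 2 or 14.

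The naive and quiescence list fell (camera adjusted p = 5.35e-09, adjusted p = 0.00761 with an estimated correlation). Of 18 members 9 fell and 1 rose (11 and 1 adjusted over the list alone). LEF1 stood at 170.0 ± 55.2 against 865 ± 237 CPM, CCR7 at 158 ± 34.5 against 493 ± 61.9 CPM and KLF2 at 413 ± 53.5 against 1144 ± 243 CPM. These 3 fell in 4 of 4 specimens, with edgeR adjusted p between 5.42e-05 and 0.00189. The Tfh programme rose (camera adjusted p = 3.01e-08, adjusted p = 0.0549 with an estimated correlation), in 7 of 26 members (11 adjusted over the list alone). Th1 genes rose (camera adjusted p = 2.52e-05, adjusted p = 0.0261 with an estimated correlation), in 3 of 5 (4 adjusted over the list alone). The SLAM family and its adaptors rose (camera adjusted p = 0.00232, adjusted p = 0.0261 with an estimated correlation). CD84, SH2D1A and FYN were the 3 of 7 members past the threshold (3 adjusted over the list alone). TCR and NFAT response genes rose (camera adjusted p = 0.00590, adjusted p = 0.0261 with an estimated correlation), in 4 of 21, with 7 up and 1 down adjusted over the list alone. The ERK phosphatase DUSP6 stood at 131 ± 35.9 against 13.6 ± 9.08 CPM (log2 3.24 ± 0.41, edgeR adjusted p = 2.03e-05, 4 of 4). Immediate early genes, which share members with the TCR and NFAT list, summed to 88984 ± 24164 CPM in nonGC and 57495 ± 21123 in naive libraries. Heat shock genes summed to 40428 ± 23777 and 26460 ± 21602 CPM in the same order, a difference within their spread over specimens. That spread ignores the pairing, and as labelled the list was called with specimen as a block, as given below. Whether these changes share a cause was not tested.

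SLAMhi GC-Tfh were compared with nonGC Tfh to ask what separates them within the Tfh compartment. As labelled, 0 of 6192 genes passed in edgeR, with or without the block, while 763 had an unadjusted p under 0.05, DESeq2 called 50, limma 3 and all libraries in 1 fit 164. The Tfh programme was higher as a list (camera adjusted p = 2.38e-14, adjusted p = 0.160 with an estimated correlation), with 13 of 26 members up adjusted over the list alone. Without specimen 9 (n = 4), MYO7A, a myosin, rose to 230.4 ± 82.6 against 5.52 ± 4.70 CPM (log2 5.29 ± 0.45, edgeR adjusted p = 3.38e-07, 4 of 4). TOX2 rose to 367 ± 83.3 against 29.3 ± 19.1 CPM (log2 3.63 ± 0.37, edgeR adjusted p = 1.17e-06, 4 of 4). MKI67 rose to 235 ± 126 against 7.90 ± 7.77 CPM (log2 4.82 ± 0.72, edgeR adjusted p = 7.7e-04, 4 of 4). The replication enzyme TOP2A (66.1 ± 36.8 against 0.837 ± 1.67 CPM), COL6A3 (70.1 ± 38.8 against 4.75 ± 5.43 CPM), NTRK3 (23.4 ± 9.32 against 1.56 ± 1.80 CPM) and CTTN (23.4 ± 8.67 against 1.61 ± 1.86 CPM) were higher too. So were AFF2 (32.6 ± 7.26 against 2.38 ± 1.59 CPM), CD200 (31.9 ± 14.8 against 2.38 ± 2.97 CPM) and carboxypeptidase M (31.8 ± 15.5 against 2.33 ± 4.65 CPM), and the edgeR adjusted p of these 7 lay between 0.00123 and 0.0282. Of the sort genes, CD4 rose (578 ± 99.2 against 313 ± 11.2 CPM, log2 0.88 ± 0.22, edgeR adjusted p = 0.0350, 4 of 4), a call lost without specimen 1, 2 or 14 (adjusted p = 0.229, 0.314 and 0.201). SLAMF1 (108 ± 30.6 against 66.5 ± 31.7 CPM, edgeR adjusted p = 0.414) and CXCR5 (60.4 ± 26.0 against 54.6 ± 30.6 CPM, 0.958) did not pass. MYO7A lies on chromosome 11, 77128264 to 77215241, and TOX2 on chromosome 20, 43914864 to 44069616. In all 63 genes rose and 56 fell, 335 changed with the block, 213 by DESeq2, and 54, 23 and 39 without specimen 1, 2 or 14.

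**Figure D3:**
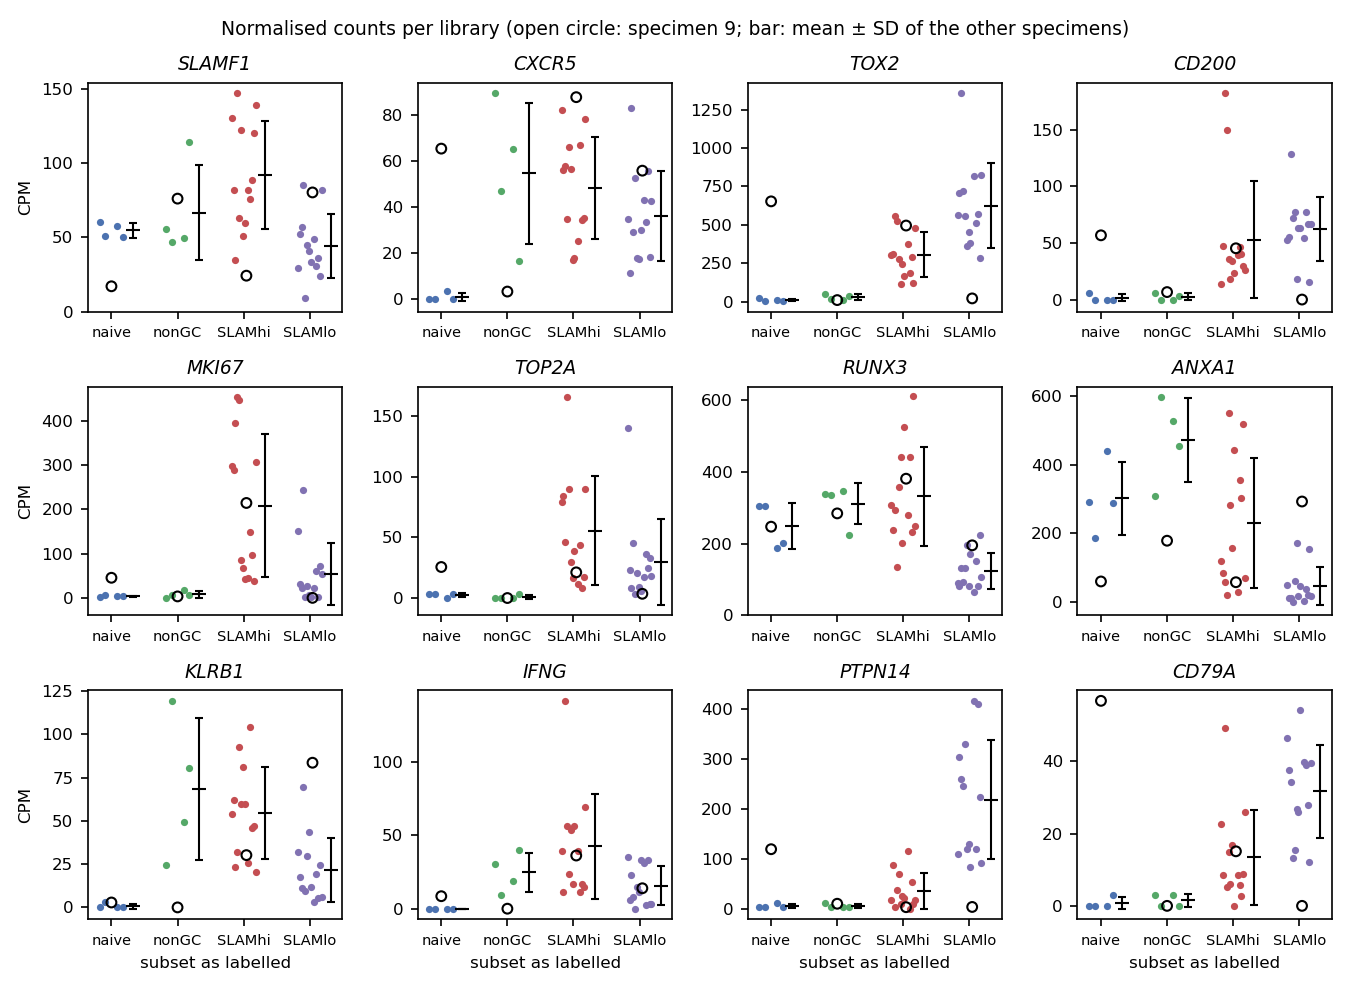
Normalised counts in CPM (y axis) of 12 genes in each library by labelled subset (x axis), with specimen 9 as an open circle and the mean ± SD of the other specimens as a bar. TOX2 averaged 29.3 ± 19.1 CPM in nonGC Tfh, 304 ± 147 in SLAMhi and 624 ± 278 in SLAMlo without specimen 9.

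The prostaglandin receptor PTGER2 fell to 2.12 ± 1.41 against 46.5 ± 16.7 CPM, and RNF157 fell too (log2 -3.65 ± 0.60, edgeR adjusted p = 9.91e-04, 4 of 4). EPHA1 (log2 -3.60 ± 0.75), TRABD2A (-3.43 ± 0.51), ADGRL1 (-3.36 ± 0.74), CD55 (-2.96 ± 0.68), TMEM30B (-2.95 ± 0.67), EPPK1 (-2.88 ± 0.57), CASP10 (-2.73 ± 0.67) and TANC2 (-2.69 ± 0.71) fell as well. The Tfh programme rose (camera adjusted p = 5.67e-22, adjusted p = 0.00372 with an estimated correlation), in 13 of 26 members (18 adjusted over the list alone). Inhibitory receptors rose (camera adjusted p = 3.91e-06, adjusted p = 0.00372 with an estimated correlation), in 4 of 6 members (4 adjusted over the list alone). These were CTLA4 (429 ± 163 against 56.7 ± 23.6 CPM, edgeR adjusted p = 1.14e-04), TIGIT (414 ± 91.8 against 122 ± 4.57 CPM, 1.1e-04), BTLA and CD200. Cell cycle genes rose (camera adjusted p = 2.34e-11, adjusted p = 0.0308 with an estimated correlation), in 5 of 11 members (9 adjusted over the list alone). The naive and quiescence list fell (camera adjusted p = 2.53e-11, adjusted p = 0.00338 with an estimated correlation), in 6 of 18 (11 adjusted over the list alone, 10 with the block). IL7R, the IL-7 receptor, stood at 516 ± 180.3 against 2506 ± 577 CPM, and KLF2 at 94.8 ± 29.6 against 413 ± 53.5 CPM. Immediate early genes were lower as a list (camera adjusted p = 3.1e-08, adjusted p = 0.124 with an estimated correlation). Of 20 members 0 fell over all genes, 9 adjusted over the list alone and 12 with the block.

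SLAMlo GC-Tfh were set against the same nonGC libraries. As labelled, 1 gene of 6192 changed in edgeR, RUNX3, lower in SLAMlo at 108 ± 51.1 against 306 ± 52.0 CPM (log2 -1.53 ± 0.27, edgeR adjusted p = 0.0272, 5 of 5). The call was lost without specimen 1, 2, 10 or 14 (edgeR adjusted p for RUNX3 of 0.457, 0.624, 0.377 and 0.247). It was kept without specimen 9, which all the fits that lost it held. With specimen as a block 4 genes changed here too, DESeq2 called 61 (45 higher, 16 lower), and all libraries in 1 fit gave 416 (215 and 201). The Tfh programme was higher as a list (camera adjusted p = 1.24e-14, adjusted p = 0.182 with an estimated correlation), in 0 of 26 members over all genes and 15 adjusted over the list alone. Without specimen 9 (n = 4), MYO7A rose to 522 ± 148 against 5.52 ± 4.70 CPM (log2 6.45 ± 0.45, edgeR adjusted p = 5.21e-09, 4 of 4). TOX2 rose to 728 ± 122 against 29.3 ± 19.1 CPM (log2 4.61 ± 0.37, edgeR adjusted p = 1.06e-08, 4 of 4), and PTPN14 to 231 ± 157 against 5.48 ± 4.56 CPM (log2 5.28 ± 0.75, adjusted p = 1.16e-04, 4 of 4). CD79A, a signalling chain of the B cell receptor (chromosome 19, 41877120 to 41881372), stood at 40.9 ± 3.92 against 1.54 ± 1.78 CPM (edgeR adjusted p = 9.6e-04, 4 of 4). NTRK3 (107 ± 53.8 against 1.56 ± 1.80 CPM), TOP2A (49.6 ± 60.2 against 0.837 ± 1.67 CPM), CTTN (69.8 ± 31.6 against 1.61 ± 1.86 CPM) and BCAT1 (68.4 ± 51.4 against 1.57 ± 3.14 CPM) were higher. NCALD (60.2 ± 33.9 against 1.54 ± 1.78 CPM) and carboxypeptidase M (68.8 ± 46.4 against 2.33 ± 4.65 CPM) were too, and the edgeR adjusted p of these 6 lay between 5.12e-06 and 0.00390. ANXA1 fell to 20.5 ± 20.3 against 472 ± 124 CPM (log2 -4.52 ± 0.49, edgeR adjusted p = 3.83e-06, 4 of 4). The calcium channel CACNA1I (1.45 ± 2.89 against 114 ± 79.8 CPM), PTGER2 (0.714 ± 1.43 against 46.5 ± 16.7 CPM), EPHA1 (1.47 ± 1.70 against 47.2 ± 21.4 CPM), LINC00861 (2.89 ± 2.36 against 78.0 ± 16.1 CPM) and IL23A (2.19 ± 2.75 against 35.8 ± 15.8 CPM) fell as well. RNF157 (log2 -4.42 ± 0.65), TRABD2A (-4.32 ± 0.57), SPG20 (-4.10 ± 0.74) and PLAC8 (-3.98 ± 0.47) completed the falls. In all 163 genes rose and 211 fell, 657 changed with the block, and 228 and 150 without specimen 1 or 2.

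By group, the Tfh programme rose (camera adjusted p = 4.75e-21, adjusted p = 0.0105 with an estimated correlation). Of 26 members 15 rose and 1, RGS1, fell (21 and 1 adjusted over the list alone). TOX stood at 423 ± 50.9 against 54.0 ± 10.1 CPM and POU2AF1, a transcriptional coactivator, at 92.4 ± 25.6 against 5.51 ± 2.97 CPM. Inhibitory receptors rose (camera adjusted p = 2.53e-05, adjusted p = 0.0105 with an estimated correlation), in 4 of 6, with 4 up and 1 down adjusted over the list alone. Memory and tissue residence genes fell (camera adjusted p = 2e-05, adjusted p = 0.0143 with an estimated correlation), in 4 of 10 (4 adjusted over the list alone), with IL7R at 241 ± 65.4 against 2506 ± 577 CPM. Migration and positioning genes fell (camera adjusted p = 0.00142, adjusted p = 0.0143 with an estimated correlation), in 4 of 18. Adjusted over the list alone 7 fell and 1 rose, and with the block 8 and 1. NF-kB targets fell (camera adjusted p = 0.00613, adjusted p = 0.174 with an estimated correlation), in 4 of 15 (4 adjusted over the list alone). Immediate early genes fell (camera adjusted p = 7.97e-07, adjusted p = 0.174 with an estimated correlation), in 6 of 20, or 15 with the block, and with 11 down and 1 up adjusted over the list alone. In the Treg and Tfr list (camera adjusted p = 0.328) 2 of 6 rose and 2 fell, the same adjusted over the list alone. Its member IKZF2 stood at 264 ± 134 against 28.9 ± 16.5 CPM (edgeR adjusted p = 5.56e-04, 4 of 4).

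Both GC-Tfh subsets were also compared with naive cells, the background of the sort. As labelled, SLAMhi differed in 105 genes in edgeR (46 higher, 59 lower), 139 with the block (60 and 79), 275 by DESeq2 (133 and 142) and 210 by limma (129 and 81). SLAMlo differed in 94 (32 and 62), 160 with the block (59 and 101), 264 by DESeq2 (125 and 139) and 187 by limma (98 and 89). The naive and quiescence list fell in SLAMhi (camera adjusted p = 1.27e-11, adjusted p = 0.0409 with an estimated correlation), in 7 of 18, with 1 up (14 and 1 adjusted over the list alone). It fell in SLAMlo (camera adjusted p = 1.78e-10, adjusted p = 0.104 with an estimated correlation), in 9, with 1 up (12 and 1 adjusted over the list alone). Leaving out specimen 1, 2, 10 or 14 took the SLAMhi count to 5, 0, 2 and 0, and the SLAMlo count to 0 in each case in edgeR, with 794, 748, 680 and 742, and 732, 638, 694 and 705 genes at an unadjusted p under 0.05. Without specimen 9 the counts were 724 (394 and 330) and 951 (483 and 468). The SLAMhi count was then 477, 411 and 456 without specimen 1, 2 or 14, and the SLAMlo count 552 without specimen 2.

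Without specimen 9 (n = 4), MAF stood at 1378 ± 212 CPM in SLAMhi and 1148 ± 87.8 in SLAMlo against 27.1 ± 6.34 in naive cells. Its log2 fold changes were 5.65 ± 0.26 and 5.37 ± 0.26 (edgeR adjusted p = 4.25e-14 and 1.2e-13, 4 of 4 specimens each). TIGIT (414 ± 91.8 and 432 ± 100.3 against 5.60 ± 1.81 CPM) and TOX2 (367 ± 83.3 and 728 ± 122 against 10.2 ± 7.84 CPM) rose likewise. KLF2 fell from 1144 ± 243 to 94.8 ± 29.6 and 98.7 ± 39.5 CPM (edgeR adjusted p = 6.9e-09 and 7.58e-09, 4 of 4 specimens each). CXCR5 stood at 60.4 ± 26.0 and 33.0 ± 14.7 against 0.897 ± 1.79 CPM (edgeR adjusted p = 3.65e-05 and 4.18e-04). IFNG was at least 4.48-fold and 2.11-fold above the floor (edgeR adjusted p = 7.77e-04 and 0.00629). The Tfh programme rose in SLAMhi (camera adjusted p = 8.46e-22, adjusted p = 0.00503 with an estimated correlation) and in SLAMlo (camera adjusted p = 1.35e-23, adjusted p = 0.00360 with an estimated correlation). In it 18 and 18 of 26 members rose (19 and 20 adjusted over the list alone). Cell cycle genes rose in SLAMhi (camera adjusted p = 1.66e-06, adjusted p = 0.0866 with an estimated correlation), in 7 of 11 (9 adjusted over the list alone). Ribosomal protein genes fell in SLAMhi (camera adjusted p = 3.36e-06, adjusted p = 0.232 with an estimated correlation) and in SLAMlo (camera adjusted p = 3.17e-08, adjusted p = 0.189 with an estimated correlation). Of 35 members 7 and 19 fell (13 and 26 adjusted over the list alone). Their summed level spread widely in naive cells, at 30806 ± 7687 CPM (20164 to 37686), so that the lowest naive library lay at the level of SLAMhi (21561 ± 2013) and SLAMlo (19638 ± 2236). These comparisons share their naive libraries, so their changes are not independent of each other.

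A last test asked where SLAMhi lies between nonGC Tfh and SLAMlo GC-Tfh, with genes defined in some specimens and measured in others. As labelled, 0 genes were higher in SLAMlo than in nonGC Tfh in edgeR (726 changed either way at an unadjusted p under 0.05, and DESeq2 called 45 higher), so the set of GC-high genes, taken from edgeR, was empty. With the block it held 2 genes, which differed by -0.43 ± 0.78 (SD, n = 9, higher in 2 specimens, exact sign-flip permutation p = 0.156). The GC-low set was RUNX3 alone, higher in SLAMhi than in SLAMlo by a log2 of 1.24 ± 0.33 (SD, n = 9) in the 9 other specimens. It was higher in 9 of 9 (exact two-sided sign-flip permutation p = 0.00391, the smallest that 9 specimens allow). With genes defined without specimen 9, the 149 genes higher in SLAMlo than nonGC differed between SLAMhi and SLAMlo by a median log2 of -0.44 ± 0.12 (SD, n = 9). They were higher in SLAMhi in 0 of 9 specimens (exact sign-flip permutation p = 0.00391). The 192 genes lower in SLAMlo than nonGC were higher in SLAMhi by 0.50 ± 0.17 (SD, n = 9, 9 of 9, exact sign-flip permutation p = 0.00391). Over all 6268 tested genes the median difference was -0.02 ± 0.09. On both sets SLAMhi libraries lay on the nonGC side of the SLAMlo libraries of the same specimen. The genes were picked for a SLAMlo level far from that of nonGC, so other cells that differ from SLAMlo could shift the same way. The test shows a difference from SLAMlo on these genes and does not place SLAMhi between nonGC and SLAMlo.

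**Figure D4:**
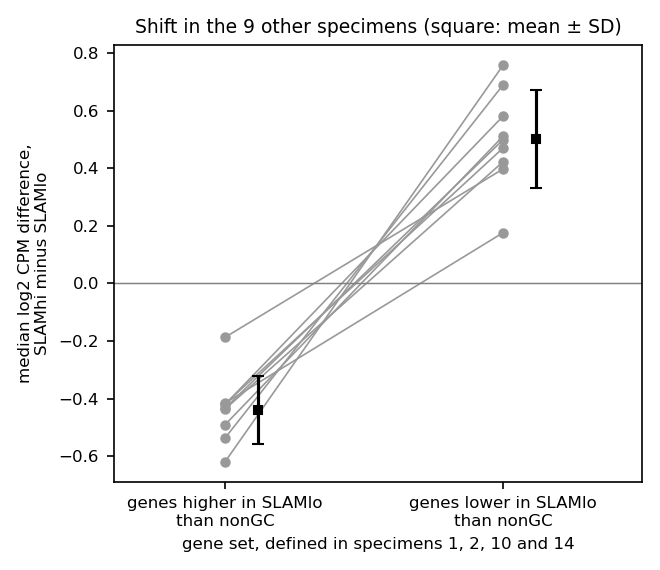
Median log2 CPM difference between SLAMhi and SLAMlo (y axis) in each of the 9 specimens with 2 subsets, over genes higher and genes lower in SLAMlo than nonGC Tfh of specimens 1, 2, 10 and 14 (x axis), lines joining the values of a specimen and squares giving the mean ± SD. The means were -0.44 and 0.50, with 0 of 9 and 9 of 9 specimens above 0.

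Specimen as a block changed the call of some lists. Heat shock genes, chaperones of the stress response, were lower in SLAMhi than in SLAMlo with the block (camera adjusted p = 0.0222, adjusted p = 0.313 with an estimated correlation) and not without it (0.234). The same list was lower with the block in SLAMhi against nonGC as labelled (camera adjusted p = 0.0142, 0.219 without it) and higher in nonGC against naive (0.00264 and 0.115). Without specimen 9 its adjusted p with and without the block was 0.0363 and 0.265 for SLAMhi against SLAMlo, 1.44e-04 and 0.0797 for SLAMhi against nonGC, and 0.00758 and 0.229 for SLAMlo against nonGC. In the last 2 comparisons 5 and 5 of 13 members fell with the block and 0 without it. NF-kB targets (camera adjusted p = 0.0151 with the block and 0.0686 without it), cholesterol synthesis (0.0151 and 0.103) and plasma cell markers (0.0445 and 0.0951) were higher in SLAMhi than SLAMlo with the block only. Plasma cell markers were so without specimen 9 too (0.0285 and 0.0659), and that list holds PRDM1, itself higher in SLAMhi. In nonGC against naive as labelled, the block brought in NF-kB targets (0.0494 and 0.140) and mitochondrial transcripts (0.0494 and 0.0613). The latter were lower as a list, but their direction rested on the naive library of specimen 10, and MT-ND4 was higher in nonGC in 3 specimens and lower in 2. In SLAMlo against naive it brought in the SLAM family (0.0452 and 0.0580) and Th1 genes (0.0452 and 0.0564). Without specimen 9 the block ended 4 calls: inhibitory receptors in nonGC against naive (0.0688 and 0.0439), ribosomal proteins in SLAMhi against nonGC (0.0586 and 0.0399), nuclear-retained RNA in SLAMhi against naive (0.0590 and 0.0446), and cell cycle genes in SLAMlo against naive (0.0593 and 0.0469). None of these calls held with an estimated correlation.

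Markers of other cells and signs of RNA quality are given as summed levels without specimen 9, and the sums were not tested between subsets. The 19 B cell markers held 62.9 ± 21.2 CPM in naive, 71.5 ± 21.3 in nonGC, 78.6 ± 22.3 in SLAMhi and 123 ± 50.1 in SLAMlo libraries. CD79A, which lay at 13.5 ± 13.2 CPM in SLAMhi and 31.7 ± 12.9 in SLAMlo (n = 13), was the 1 B cell marker with enough counts to be tested in the fit of 4 subsets, and was not tested between SLAMhi and SLAMlo. Germinal centre B cell markers held 34.4 ± 25.2, 70.2 ± 9.09, 45.2 ± 21.7 and 63.5 ± 29.4 CPM in the same order, and plasma cell markers 441 ± 181, 578 ± 137, 554 ± 130.1 and 362 ± 127. Myeloid and dendritic markers held 57.1 ± 36.0, 78.0 ± 57.2, 71.6 ± 30.4 and 77.1 ± 41.6 CPM, and stroma and FDC markers 146 ± 53.7, 50.05 ± 15.8, 39.7 ± 17.5 and 56.0 ± 37.5. The plasma cell list holds PRDM1, itself higher in SLAMhi, while JCHAIN stood at 0.46 ± 1.12 CPM in SLAMhi and 0.41 ± 1.48 in SLAMlo. The stroma list holds PECAM1, itself higher in naive cells than in nonGC and SLAMhi. These sums therefore cannot be read as amounts of plasma or stromal cells. CD8 and NK markers (4.71 ± 1.66, 8.86 ± 7.30, 11.3 ± 20.7 and 8.60 ± 9.79 CPM) and erythroid and platelet markers (8.85 ± 5.56, 2.46 ± 3.19, 2.85 ± 2.58 and 5.67 ± 8.30 CPM) had no member with enough counts to be tested. Mitochondrially encoded transcripts summed to 88618 ± 104112, 42830 ± 7490.4, 32328 ± 6315 and 41811 ± 8162 CPM, where the naive mean and its spread rest on the library of specimen 10, with 20.2% of its counts.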

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

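Of the tests in this part, those of exchanged labels, of B cells, of library complexity and of swaps in the comparisons with 4 subsets were chosen only after the result was seen. Leaving out specimen 9 was a leave-one-out choice made beforehand for the comparisons with 4 subsets, while its use as a repeat with tests of its own, and any fit without it of SLAMhi against SLAMlo, came after. A gap test (Dixon, 95%) asked whether the highest or lowest library of a group lay far from the others. It was run on 85 sets of 5 libraries, of which 16 held such a library. It was also run on 109 sets of 4 without specimen 9, of single genes only, of which 19 did. Chance gives about 1 in 20 for continuous values. A gene with counts in only 1 of 4 libraries is flagged by construction, so the 19 of 109 cannot be set against that rate. Of the 16, 11 lay in specimen 9 (7 in the library labelled naive and 4 in that labelled nonGC) and 4 in the naive library of specimen 10.

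In the library labelled naive in specimen 9, the mean log2 CPM was 7.159 for the Tfh programme (nearest other naive library 5.238), 5.692 for inhibitory receptors (4.613), 7.103 for TCR and NFAT response (6.272), 4.572 for cell cycle (3.946) and 6.79 for naive and quiescence (8.531). CXCR5 stood at 65.3 CPM (3.588) and SLAMF1 at 17.04 (50.13). In the library labelled nonGC in specimen 9, the Tfh programme lay at 4.944 (5.547), migration and positioning at 5.862 (6.113), ribosomal proteins at 9.361 (8.861) and CD4 at 214.7 CPM (303.9). The naive library of specimen 10 held 20.22% mitochondrial counts (4.205), with mean log2 CPM of 13.1 for mitochondrially encoded genes (10.56), 7.012 for NF-kB targets (7.632) and 8.703 for nuclear-retained RNA (8.261). Interferon response genes averaged 6.698 in the naive library of specimen 1 (5.323).

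Library and list measures were not tested in sets of 4, and the 20.22% of specimen 10 stood apart there too (3.989, 4.039 and 2.806 in the naive libraries of specimens 1, 2 and 14). The gaps of single genes without specimen 9 are in CPM. Among naive libraries these were CXCR5 (3.588 in specimen 10, the others 0), KLRB1 (2.989 in specimen 2, the others 0) and TMEM200A (2.989 in specimen 2, the others 0). Among nonGC libraries these were AFF2 (0 in specimen 2, nearest 3.078), BCAT1 (6.284 in 2, nearest 0), carboxypeptidase M (9.304 in 10, nearest 0), DACT1 (3.101 in 10, nearest 0), MYO7A (12.57 in 2, nearest 3.348), PTPN14 (12.31 in 1, nearest 3.348) and TOP2A (3.348 in 14, nearest 0). In SLAMhi, specimen 10 was low in MKI67 (45.16, nearest 289.5) and TOP2A (11.29, nearest 79.24), and specimen 14 in PTGER2 (0, nearest 2.811). In SLAMlo these were CACNA1I (5.78 in 2, nearest 0), CTTN (117 in 10, nearest 57.77), PTGER2 (2.854 in 10, nearest 0), RNF157 (23.29 in 1, nearest 2.89), SPG20 (15.2 in 14, nearest 0) and TOP2A (139.8 in 1, nearest 23.12). Most of these levels rest on fewer than 10 counts.

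Other splits of the same libraries were fitted to ask how often they gave as many genes. For SLAMhi against SLAMlo, 1 of 100 splits, the real one with 38 genes, gave as many (highest other 2), and without specimen 9 1 of 100 for 78 genes (highest other 6). These splits ignore that libraries of a specimen are paired. Among swaps within specimens, drawn from 8192 possible, 1 of 100, the real one, gave as many as the blocked 283. The highest other gave 166 with specimens 7 and 9 exchanged. Without specimen 9, 1 of 100, drawn from 4096, gave as many as the blocked 378 (highest other 47). Both shares lie under 0.05, which makes chance unlikely for the blocked counts without excluding it. As labelled, 3 of 100 splits gave at least the 1 gene of nonGC against naive (highest other 233), 4 of 100 the 1 of SLAMlo against nonGC (68), 4 of 100 the 105 of SLAMhi against naive (157), and 3 of 100 the 94 of SLAMlo against naive (151). The highest of these moved specimen 9 in each of the 4 comparisons. For SLAMhi against nonGC the count was 0 in edgeR (763 at an unadjusted p under 0.05, 50 by DESeq2, 3 by limma), which all 100 splits and all 16 swaps reach by construction, so they decide nothing. Without specimen 9, 1 of 35 splits, again ignoring the pairing, gave as many genes in each of the 5 comparisons, with the highest others at 0, 0, 0, 1 and 13 against 192, 119, 374, 724 and 951.

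Swaps within specimens were too few for a share under 0.05 in the 5 comparisons with 4 subsets. As labelled there were 16, of which 3 gave at least the blocked 4 genes of nonGC against naive (highest other 309), 2 the 4 of SLAMlo against nonGC (57), 2 the 139 of SLAMhi against naive (197) and 2 the 160 of SLAMlo against naive (1132). Exchanging specimen 9 alone gave the highest other in these 4. In each, that count was above the blocked count as labelled, so these counts depend on how specimen 9 is labelled. Each swap exchanges 2 labels of a specimen and does not test an exchange of 3. Without specimen 9 there were 8, of which 1, the real one, gave as many in each comparison, with blocked counts of 352, 335, 657, 1026 and 1217 against highest others of 1, 0, 1, 1 and 1.

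The first pattern weighed was that 3 libraries of specimen 9 matched other subsets. An exchange of labels within the specimen needs all 3 to match another of the 3 subsets, and 3 did, while over the 195 genes that vary between specimens 4 of 4 matched their own specimen. A mixture of the labelled with the matched subset was to be excluded, as written beforehand, if the share of the labelled subset's excess stayed within 10 percentage points of the matched subset's highest other library in any of the 3 libraries. The shares were 6.73%, 5.89% and -1.37% in the libraries labelled naive, nonGC and SLAMlo, against -0.187%, 4.53% and -0.356%, so a small residue stays open. An exchange of the 3 labels is a candidate explanation, found and tested on the same data, and the labels were not changed. No biological explanation was tested.

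The second was CD79A in GC-Tfh libraries, which may come from the T cells or from B cells left by the sort. From naive to SLAMlo in specimens 1, 2, 10 and 14, CD79A rose by 40.1 ± 4.55 CPM (SD, n = 4) and the 18 other B cell markers together by 21.8 ± 45.7, from 62.1 ± 21.6 to 83.9 ± 30.5, a ratio of 0.544. From nonGC to SLAMlo, CD79A rose by 39.4 ± 2.98 CPM and the 18 others by 13.96 ± 43.1, while the sum of MS4A1, BANK1, PAX5 and IGKC, picked after their values were seen, changed by -6.64 ± 18.04, from 15.6 ± 14.7 to 8.99 ± 10.9. Both of these changes lie within their spread and decide nothing. Over all libraries without specimen 9, MS4A1 stood at 10.2 ± 7.99 CPM in nonGC and 11.5 ± 9.12 in SLAMlo, CD79B at 9.53 ± 5.17 and 15.5 ± 10.3, and CD74 at 286 ± 122 and 334 ± 98.2. B cells, which the CD4 sort would remove, cannot be told apart from expression in T cells. In GENCODE 29, 0 annotated genes overlap CD79A, which argues against reads of an overlapping gene. The annotation used for counting is not given, so such reads are not excluded.

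The third was the lower level of mitochondrially encoded transcripts in SLAMhi than in SLAMlo. If library complexity alone were the cause, the difference would go opposite ways where SLAMhi had more and where it had fewer detected genes. In the 6 specimens where it had more, the mean log2 difference was -0.24 ± 0.21 (SD, n = 6, lower in 5, value -0.241). In the 8 where it had fewer it was -0.31 ± 0.27 (SD, n = 8, lower in 7), and over 14 specimens the sign-flip permutation p was 0.00134. Both means lay below 0, which argues against complexity alone, as measured by detected genes. Complexity is not excluded, since the 6 specimens were not tested on their own. A stress response during dissociation or sorting stays open, because the mitochondrial and heat shock differences correlated with rho = 0.464 (permutation p = 0.0960, adjusted 0.192) and r = 0.389 (permutation p = 0.171, adjusted 0.18) over 14 specimens, and r = 0.310 without the 2 farthest. Both tests kept specimen 9 as labelled, among the 8 with fewer detected genes, and were not repeated without it. The difference in SLAM between the subsets, which the design names, stays open and untested.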

How the results depend on the processing

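Limma, the alternatives of the repeat without specimen 9, the fits without specimens 3, 9 and 13, and the leave-one-out fits of SLAMhi against SLAMlo were chosen after seeing the data, while leaving out specimen 9 in the comparisons with 4 subsets was chosen before. As labelled, 62 of 79 counts moved by over 1.5 times, 5458 of 6143 values of named genes kept their direction and side of the threshold, 458 came past it, 227 fell behind it and 0 reversed. Without specimen 9, 26 of 72 counts moved, 4383 of 5852 gene values were kept, 102 came past, 1365 fell behind and 2 reversed. The first was INSIG1 in SLAMhi against SLAMlo, at log2 -0.02998 in the specimens with 4 subsets only (edgeR adjusted p = 0.990). Its adjusted p was 0.0149 in the blocked fit, the base here, and 0.0334 to 0.990 over 22 alternatives. The second was NFKB1 in SLAMhi against naive, at log2 0.006387 with all libraries in 1 fit (edgeR adjusted p = 0.995). Its adjusted p was 0.0192 in the fit without the block, the base here, and 0.00703 to 0.995 over 10 alternatives. The cause was not tested. Of 52 lists called as labelled 8 were called with an estimated correlation, and of 70 without specimen 9 25 were. With specimen as a block 52 and 66 of these were called, with 10 and 4 added, as given in the report, and the block changed no other list call.

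For SLAMhi against SLAMlo (38 genes), counts were 283 with the block, 73 by DESeq2, 842 with no filter on low counts, 0 in edgeR in specimens with 4 subsets (193 at an unadjusted p under 0.05), 16 in the 9 others, and 71 without specimens 3, 9 and 13 or 395 with the block as well. Leaving out 1 specimen gave 16 to 78. For nonGC against naive (1) they were 4 with the block, 27 by DESeq2, 51 with no filter, 10 from all libraries in 1 fit, and 0 to 192 leaving out 1 specimen. For SLAMhi against nonGC (0) they were 50 by DESeq2, 154 with no filter, 3 by limma, 164 from all libraries, and 0 to 119. For SLAMlo against nonGC (1) they were 4 with the block, 61 by DESeq2, 146 with no filter, 416 from all libraries, and 0 to 374. For SLAMhi against naive (105) they were 275 by DESeq2, 330 with no filter, 210 by limma, 419 from all libraries, and 0 to 724. For SLAMlo against naive (94) they were 160 with the block, 264 by DESeq2, 297 with no filter, 187 by limma, 468 from all libraries, and 0 to 951. The highest of each range left out specimen 9. Subsets of specimens have fewer samples, and the cause of the other moves was not tested.

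Without specimen 9, SLAMhi against SLAMlo (78) gave 378 with the block, 130 by DESeq2, 883 with no filter, 1 in specimens with 4 subsets, 395 with the block also without specimens 3 and 13, and 49 to 85 leaving out 1 more. The count was 352 with the block, 121 from all libraries and 77 to 165 for nonGC against naive (192). It was 335 with the block, 213 by DESeq2, 189 with no filter, 189 from all libraries and 23 to 104 for SLAMhi against nonGC (119). It was 657 with the block and 150 to 340 for SLAMlo against nonGC (374), 411 to 561 for SLAMhi against naive (724) and 552 to 804 for SLAMlo against naive (951). The 20 genes with the largest changes between SLAMhi and SLAMlo as labelled kept their direction in every setting that tested them. All 20 were called by DESeq2, with the block, with no filter and with code prefix, 19 with RLE factors, 16 by limma, 11 of 19 in the 9 specimens with 2 subsets and 0 of 18 by edgeR in those with 4, and 11 to 17 were called leaving out 1 specimen other than 9. The shift of GC-low genes as labelled rests on RUNX3, so a fold threshold or a mean over genes cannot move it. It was 1.24 with RLE factors and 1.11 with the 2 genes of the blocked fit, in 9 of 9 specimens each (exact permutation p = 0.00391). Both shifts without specimen 9 kept their direction and side of the threshold in 10 of 10 alternatives. As labelled, the GC-high set was empty and gave no value, and at an adjusted p threshold of 0.01 no set held a gene. Depth limits these results, since 1 count was 2.97 CPM.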

Other observations

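The hypothesis on the size of the SLAMF1 difference was written before its result was seen, and the repeats without specimen 9 with tests of their own were chosen after. Without specimen 9, CXCL13, the chemokine that draws B cells into follicles, stood at 423 ± 664 against 1.57 ± 3.14 CPM in SLAMhi against nonGC (n = 4, 4 of 4). The SD in SLAMhi exceeded the mean, so the level was very uneven and the mean does not stand for each library. CXCL13 passed with specimen as a block (edgeR adjusted p = 8.05e-04) and not without it (0.236). The helper cytokine and costimulation list was higher in SLAMhi than naive cells (camera adjusted p = 0.0130, adjusted p = 0.0644 with an estimated correlation), in 3 of 9 members (4 adjusted over the list alone), with the ligand TNFSF14 at 46.1 ± 17.9 against 4.53 ± 5.18 CPM (edgeR adjusted p = 0.00115, 4 of 4). Immediate early genes were higher in nonGC than in naive cells (camera adjusted p = 2.05e-06, adjusted p = 0.144 with an estimated correlation), in 3 of 20 members (5 adjusted over the list alone). KLF6 stood at 5226 ± 777 against 2421 ± 552 CPM (edgeR adjusted p = 0.00422, 4 of 4). The apoptosis list was higher there (camera adjusted p = 0.0218, adjusted p = 0.0613 with an estimated correlation), in 2 of 12 members (3 adjusted over the list alone), with the death receptor FAS at 48.1 ± 6.78 against 5.46 ± 2.75 CPM (edgeR adjusted p = 2.39e-04, 4 of 4). Treg and Tfr genes were higher too (camera adjusted p = 0.00232, adjusted p = 0.0261 with an estimated correlation), in 1 of 6 (3 adjusted over the list alone), with TNFRSF1B at 136 ± 20.6 against 35.9 ± 23.7 CPM (edgeR adjusted p = 0.00247, 4 of 4). Of 2 tested Th2 genes, CCR4, a chemokine receptor, stood at 83.6 ± 18.5 against 13.98 ± 10.7 CPM (edgeR adjusted p = 0.00942, 4 of 4) and GATA3 at 232 ± 40.9 against 139 ± 19.1 CPM (0.111, and 0.0374 with the block).

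Between SLAMhi and SLAMlo without specimen 9, ribosomal protein genes (camera adjusted p = 0.00113, adjusted p = 0.414 with an estimated correlation) and interferon response genes (camera adjusted p = 0.0117, adjusted p = 0.331 with an estimated correlation) were higher as lists. NF-kB targets (camera adjusted p = 0.0289, adjusted p = 0.310 with an estimated correlation) and TCR and NFAT response genes (camera adjusted p = 0.0471, adjusted p = 0.130 with an estimated correlation) were higher too. In these 4 lists 0, 0, 0 and 1 members rose by edgeR, and 0, 0, 1 and 2 adjusted over the list alone. CD6, a T cell surface receptor, was that member, at 432 ± 68.0 against 313 ± 53.1 CPM (log2 0.46 ± 0.12, edgeR adjusted p = 0.0318, 12 of 13). The unfolded protein response list was higher (camera adjusted p = 0.00747, adjusted p = 0.0831 with an estimated correlation), in 4 of 11 members adjusted over the list alone, and lower in SLAMlo than in nonGC (camera adjusted p = 0.00142, adjusted p = 0.174 with an estimated correlation), in 5. Nuclear-retained RNA was lower in SLAMhi than in nonGC (camera adjusted p = 3.57e-04, adjusted p = 0.103 with an estimated correlation), in 3 of 8 adjusted over the list alone. Th17 genes were called in no comparison (lowest camera adjusted p = 0.0623 without specimen 9), nor were oxidative phosphorylation (0.0797) or, without the block, plasma cell markers (0.0659), cholesterol synthesis (0.262) and heat shock (0.0797). Single tested markers stood for the stroma list, where PECAM1 fell from 112 ± 61.2 CPM in naive to 14.9 ± 5.29 in SLAMhi (edgeR adjusted p = 0.00556, 4 of 4), and the myeloid list, where IRF8 did not pass in SLAMlo against nonGC (42.8 ± 54.0 against 17.6 ± 11.6 CPM, edgeR adjusted p = 0.455). The 1 tested germinal centre B cell marker did not pass between SLAMhi and SLAMlo.

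A hypothesis was tested: that the sort's reach in SLAMF1 set the shift of GC-low genes between SLAMhi and SLAMlo. Over the 9 specimens with 2 subsets, the SLAMF1 difference and the shift of GC-low genes correlated with rho = 0.183 (exact permutation p = 0.644, adjusted 0.644) and r = 0.486 (exact permutation p = 0.18, adjusted 0.18), or r = -0.156 without the 2 farthest. Adjustment covered 2 relations, this one and that of the mitochondrial and heat shock differences given above. A rho above 0 that does not pass decides neither way, so the hypothesis stays open.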
